A study of Homo sapiens with 6 samples.

How the data were processed

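Gene expression was measured on 6 Affymetrix HG-U133 Plus 2.0 arrays, with 1 colour, hybridised with labelled RNA of the Awells cell line. Per the labels, total RNA was isolated with TRIzol and an RNeasy column, checked on a Bioanalyzer, labelled with an ENZO kit and scanned on a GeneChip scanner. Per the labels, the authors scaled the signal intensity over all probe sets of each array to a target of 100. The program that summarised the probes into probe sets is not given in the sources used here. The deposited intensity values are on a linear scale and never negative. After leaving out the highest and lowest 2% of probe sets, the mean of each array was 100.01, the same on all arrays. Experiment descriptions of the arrays name the chip type, and their lot, date and scanner fields are empty, so no batch could be read from them. Arrays were grouped by the medium and the hours in their labels, and replicate numbers are those of the labels.

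Of the 54675 probe sets, 62 are controls, 41091 had exactly 1 gene symbol in the platform annotation of 2016, 1801 had several and 11721 had none. Entrez identifiers of 41037 of the 1-symbol probe sets were found in the RefSeq gene table (GRCh38.p14), which changed 0 symbols. The arrays name no genome build, so no coordinates are given. Probe sets with several symbols named no gene. For each of 19775 genes, the probe set with the highest mean log2 signal was used, and genes with a mean signal of at least 50 over the 6 arrays were tested, which left 9708. Bright probe sets respond less to changes, and some probe sets, with names ending in _x_at or _s_at, can bind related transcripts, such as those of HLA genes.

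Log2(signal + 16) was compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Contrasts at 24 h, between times and between the effects came from a model with 4 group means, whose 2 residual degrees of freedom come from the 24 h arrays alone. The effect over both times came from a model with time and starvation terms, which compares 3 starved with 3 control arrays. It has 3 residual degrees of freedom. Of these, 2 come from the 24 h replicates, and the rest is the difference between the 6 h and 24 h effects. At 6 h, genes at least 2-fold apart were counted without a test. A total of 30 gene lists were fixed before the data were examined, and 27 had at least 5 measured genes. They were tested with camera (limma), with a preset correlation of 0.01 between genes and with a correlation estimated from the residuals, and with fry. With an estimated correlation, camera also takes its degrees of freedom from the few residuals of the arrays. That test therefore had little power, and a list that fails it is not shown to be unshifted. Overlaps between lists were kept, such as ATF3 in 2 lists. For each pair of arrays, the median of a list was placed among 10000 random lists matched on signal in 20 bins. Lists whose median, mean and camera direction differed in sign were MHC class I, ER chaperones and histones at 24 h, and lysosome, NRF2, histones and MHC class I over both times.

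The rule for named genes was also fixed before the data were examined. It took the 10 largest rises and falls at 24 h and over both times (those past the threshold first), the 8 largest each way at 6 h with a higher array of at least 100, and 5 each way past the threshold for the contrasts with time. It added up to 4 passing members of each list at 24 h, or else the 2 with the largest change, and a set of antigen presentation, lysosomal, autophagy, stress and reference genes that were always named. Genes outside the rule are said to be so.

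The code was tested on simulated values for the 9708 genes with the fitted spread, in 10 simulations with 200 changed genes each. At 24 h, changes of log2 1, 2 and 3 were recovered in 0.149%, 27.5% and 66.7% of cases, and 5.45% of calls were unchanged genes. Over both times the shares were 4.93%, 66.3% and 89.5%, and 5.07% of calls were unchanged genes. A shift of 1 in the ATF4 list was called by camera in 10 of 10 simulations, with 0 calls of other lists. Genes were simulated as independent of each other and with the same spread on all arrays. In the data, the correlation estimated at 24 h ran from -0.0798 (plasma cell genes) to 0.99 (histones), with 0.353 for the ATF4 list. The simulations therefore cannot show how often lists of correlated genes are called wrongly.

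Alternatives were another normalization (quantile), offset, filter and summary of probe sets, other variants of limma and of the list tests, a term for the replicate number, and leaving out each array in turn. Scaling to the 9 hybridization control probe sets, leaving out both arrays numbered 2, the term for the replicate number in the contrasts with time, and the alternatives for lists over both times were added after the data were seen.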

Results

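The series measured messenger RNA in the B-lymphoblastoid cell line Awells, an established line of B cells immortalised with Epstein-Barr virus, after the cells had been placed in Hank's balanced salt solution. This solution holds salts and glucose but neither amino acids nor serum, and the labels give its purpose as inducing autophagy, the delivery of cell contents to lysosomes for breakdown. The series title sets this beside the presentation of intracellular proteins on MHC class II molecules. Control cells stayed in DMEM with fetal calf serum. At 6 h there was 1 starved and 1 control array, and at 24 h there were 2 of each, so that 6 arrays were compared. Each array gave a scaled signal for 54675 probe sets, and 9708 genes were bright enough to be tested. The number of arrays limits the precision of every value below, and the 6 h arrays have no replicate. Nothing in the labels says that arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. Over both times, that spread also holds the difference between the 6 h and 24 h effects, which weighs against genes whose effect changed with time. Changes are differences of log2(signal + 16), a scale that understates the change of dim genes, folds are taken on the same scale, and a pair means a starved and a control array of the same time and number.

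The arrays differed in ways that their groups do not describe. The median signal over all probe sets was 37.8 on the starved 24 h array 2 and 31.0 on the control 24 h array 2, against 21.7 to 26.3 on the other arrays. Between the starved 24 h arrays, 1692 genes were at least 2-fold apart, and between the control 24 h arrays 500 genes were. The correlation across genes was 0.882 for the starved pair of replicates and 0.941 for the control pair of replicates. The ratio of 3' to 5' signal, a sign of RNA integrity, lay between 0.858 and 1.17 for GAPDH and ACTB on all 6 arrays. At 24 h, hybridization controls, which are added to each sample in equal amounts, were 1.56-fold higher on the starved arrays, and probe sets for ribosomal RNA were 2.08-fold higher.

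Over both times, CTH had the largest rise of the genes that passed. This enzyme makes cysteine from cystathionine, and its messenger RNA was 13.0-fold higher, with a change of 3.70 ± 0.39 (SE, adjusted p = 0.00899, limma), and it was higher in all 3 pairs. INHBE, an inhibin subunit, rose by 3.51 ± 0.36 and CREBRF, a regulator of the transcription factor CREB3, by 3.50 ± 0.28. TNFRSF10D, a decoy receptor for the death ligand TRAIL, rose by 3.10 ± 0.21, with the smallest adjusted p of all genes (0.00278). AQP9, a channel for water and glycerol, rose by 3.08 and CHAC1, an enzyme that degrades glutathione, by 3.04. ZBTB10 rose by 2.90, TNFAIP6 by 2.65, RFPL3S by 2.65 and the stress-induced transcription factor ATF3 by 2.59. The largest fall was seen with a probe set annotated to MIR142, at -3.00 ± 0.26 (adjusted p = 0.00464), which would detect a polyadenylated precursor and not the mature microRNA. SLC25A15, the mitochondrial ornithine carrier, fell by 2.38, the signalling adaptor TRAF5 by 2.29 and the cell-cycle gene CDCA7 by 2.23. TMEM177 fell by 2.16, the homeobox gene HMX2 by 2.13, and PIGM and CHST14, enzymes of GPI anchors and dermatan sulfate, by 2.05 each. CHAC2 fell by 1.98 and PWP2, a factor of ribosome assembly, by 1.92. These sizes depended on the processing, and some genes had dim signals in 1 group, such as MIR142 with 7.3 and 9.4 on the starved 24 h arrays. Over the alternatives MIR142 ranged from -3.96 to -1.82, SLC25A15 from -3.60 to -1.47, TRAF5 from -2.97 to -0.93 and PWP2 from -2.31 to -0.66. On the higher side CTH ranged from 3.31 to 4.29, INHBE from 2.65 to 4.28, CREBRF from 2.16 to 3.75 and TNFRSF10D from 2.73 to 3.31.

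In total 301 genes changed over both times at an adjusted p under 0.05 (limma with a time term), 192 higher and 109 lower in starved cells. All 301 had the same direction in all 3 pairs, and 293 changed at least 2-fold. Both are largely built in, because these genes were chosen by their p on the same arrays. This count depended on single arrays. Without the starved or the control 6 h array no gene passed, with 1923 and 1917 genes at an unadjusted p under 0.05. Both of these fits repeat the 24 h comparison by construction, because the time term takes up the remaining 6 h array. The count was 12 without the starved 24 h array 1, 10 without control 24 h array 1, 2 without control 24 h array 2, and 1015 without the starved 24 h array 2. It was 1600 without both arrays numbered 2, an alternative chosen after seeing the data. Quantile normalization gave 172 higher and 59 lower genes, and scaling to the hybridization controls, also chosen after seeing the data, gave 95 higher and 617 lower. The count was 88 without a filter on signal, 94 with the mean of all probe sets of a gene and 110 without an intensity trend. With a replicate block, which assumes that equal numbers pair the arrays although the labels do not say so, it was 1002 (471 higher, 531 lower).

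**Figure D1:**
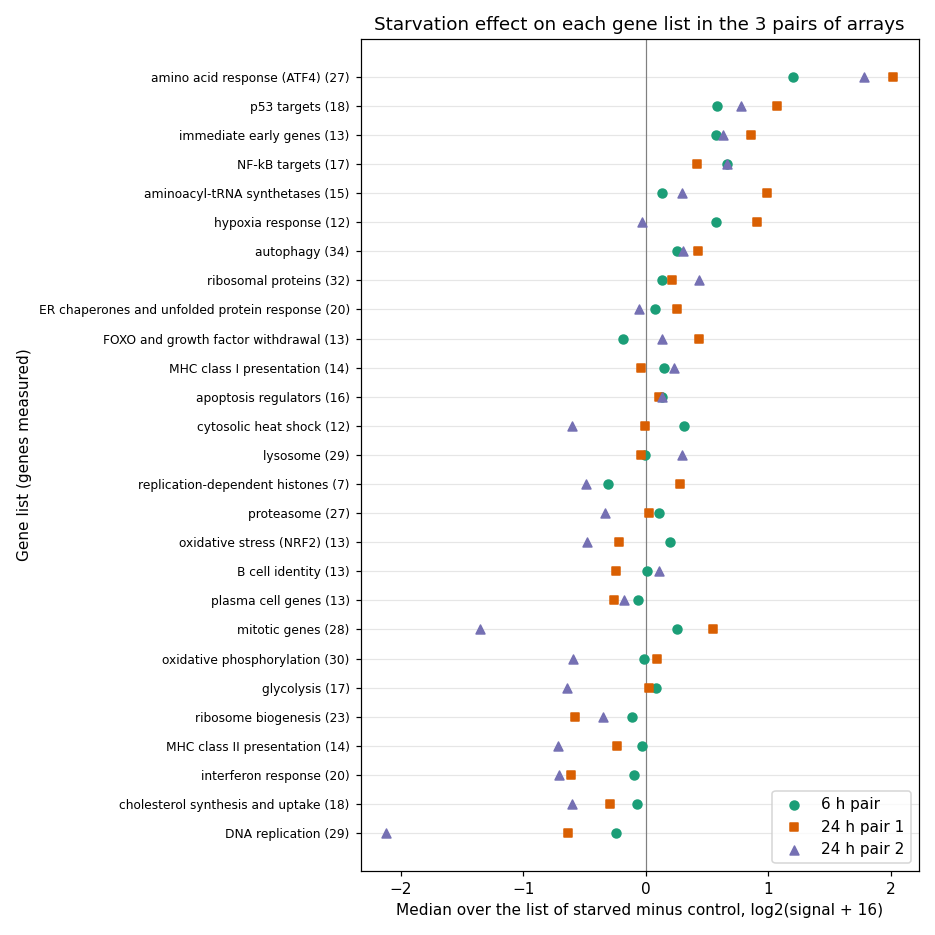
Median starved minus control difference of log2(signal + 16) for 27 gene lists fixed before the data were examined (y axis, with the number of genes measured), 1 point for each pair of arrays. The ATF4 list lies highest in all 3 pairs, at 1.20, 2.02 and 1.78, and the mitotic genes lie at 0.25 and 0.55 in 2 pairs and at -1.35 in the 24 h pair 2.

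The list of the amino acid response, genes driven by the transcription factor ATF4 when amino acids are short, had the highest median of the 27 lists. Of its 27 measured genes, 17 rose over both times and 10 did not pass. Adjusted over the list alone, 22 were higher and 1 was lower. The median change was 1.77 over both times, and it was 1.20 in the 6 h pair, 2.02 in the 24 h pair 1 and 1.78 in the 24 h pair 2. Besides CTH and CHAC1, the gene of asparagine synthetase ASNS rose by 2.27 ± 0.37 (adjusted p = 0.0298). DDIT3, which encodes the stress factor CHOP, had a change of 0.65 that did not pass (adjusted p = 0.165). The members named next, apart from SLC7A11, fall outside the rule for named genes and were picked after their values were seen. ATF4 itself rose by 1.78 and its partner CEBPB by 2.14, the leucine sensor SESN2 by 2.51, and the serine synthesis genes PSAT1, PHGDH and PSPH by 2.23, 2.03 and 1.73. The amino acid transporters SLC38A2, SLC3A2, SLC7A5, SLC7A11, SLC7A1 and SLC1A5 rose by 2.13, 2.08, 1.83, 1.82, 1.52 and 1.42. The list passed camera with its preset correlation (adjusted p = 2.71e-22) and did not with an estimated correlation (adjusted p = 0.261).

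**Figure D2:**
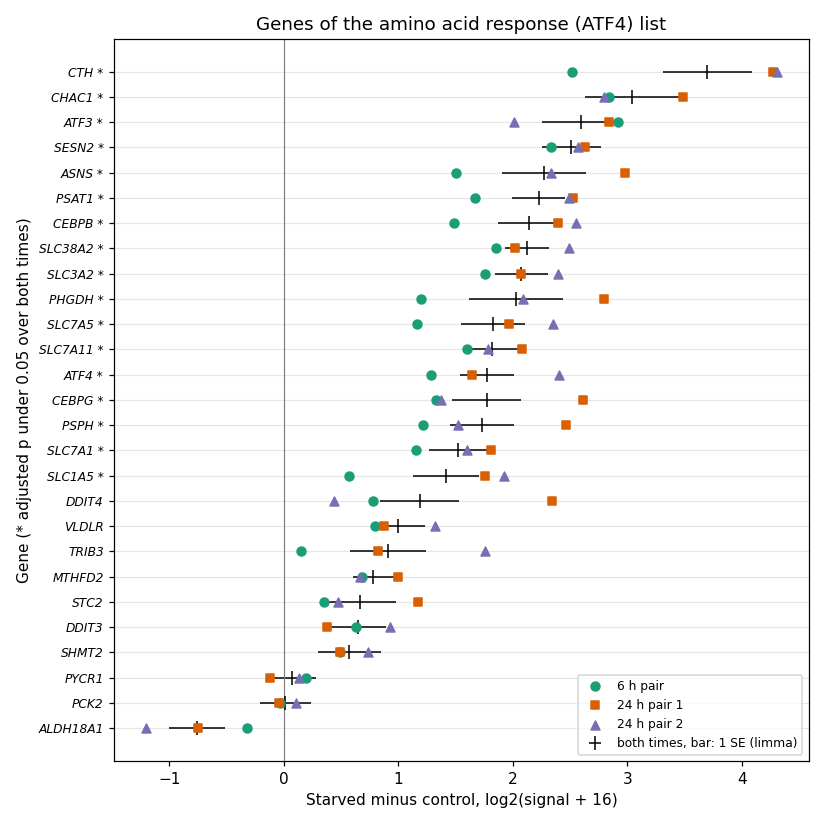
Starved minus control difference of log2(signal + 16) for the 27 measured genes of the ATF4 list, with 1 point per pair and a bar for 1 SE of the change over both times (limma, 3 starved and 3 control arrays). Of these genes, 24 were above 0 in all 3 pairs and ALDH18A1 was below 0 in all 3.

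Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had 4 of 15 genes higher over both times and none lower, and 7 higher and 1 lower adjusted over the list alone. CARS1 rose by 1.98 ± 0.28 and WARS1 by 1.79 ± 0.28. The list passed with a preset correlation (adjusted p = 0.000683) and did not with an estimated one (adjusted p = 0.575). Of 20 genes of ER chaperones and the unfolded protein response, 3 rose and none fell. Adjusted over the list alone, 3 were higher over both times, and 3 were higher and 3 lower at 24 h. The genes that rose were PPP1R15A, which restores translation after stress, at 2.34 ± 0.31, and HERPUD1 and DNAJB9, picked after their values were seen, at 1.70 and 1.25, while CRELD2 had -1.69 and did not pass (adjusted p = 0.104). This list was not shifted (adjusted p = 0.122).

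Targets of p53 had 5 of 18 genes higher and none lower, and 11 higher adjusted over the list alone. TP53INP1, a stress-induced nuclear protein, rose by 1.96 ± 0.26 and TNFRSF10B, a death receptor for TRAIL, by 1.76 ± 0.24. Among immediate early genes 3 of 13 rose, and 9 adjusted over the list alone, with ATF3 the largest and KLF6 at 1.56 not passing (adjusted p = 0.0581). Among NF-kB targets 2 of 17 rose, and 5 adjusted over the list alone. These were ICAM1 at 1.17 ± 0.23 and TNFAIP3 at 0.92 ± 0.18, which are an adhesion molecule and an inhibitor of NF-kB. The hypoxia list had 3 of 12 genes higher, and 4 adjusted over the list alone, with VEGFA at 1.92 ± 0.21 and BHLHE40 at 1.40 ± 0.25. All 4 lists passed with a preset correlation, with adjusted p = 6.47e-07, 1.33e-05, 6.87e-05 and 0.000683 in this order. With an estimated correlation none did (adjusted p = 0.261, 0.261, 0.472 and 0.472).

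Lists of growth factor withdrawal and apoptosis were not shifted over both times (adjusted p = 0.0957 and 0.0545), but each had genes that rose. In the FOXO list 2 of 13 rose, and 3 adjusted over the list alone, namely the cyclin CCNG2 (2.31 ± 0.48) and KLHL24 (1.61 ± 0.26) among all genes. Among 16 apoptosis regulators 2 rose, and 6 were higher and 1 lower adjusted over the list alone. These were the survival gene BCL2 (1.83 ± 0.37) and BMF, which encodes a killer protein that binds BCL2 (1.70 ± 0.29). In the NRF2 list the cystine transporter SLC7A11, also a member of the ATF4 list, was the only 1 of 13 genes to rise, while the quinone reductase NQO1 had -0.91 and did not pass (adjusted p = 0.113). Of 17 glycolysis genes PFKP, a phosphofructokinase, fell by 1.06 ± 0.21, and ENO2 had -0.59 without passing (adjusted p = 0.17). Both lists were unshifted (adjusted p = 0.823 and 0.616).

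Few markers of other cell types were among the genes tested. Of 12 T and NK cell markers only PRF1 was measured, at -0.21, and of 12 monocyte and macrophage markers only VCAN, at 0.63, and neither passed (adjusted p = 0.673 and 0.27). Of 9 fibroblast markers 4 were measured. COL1A1, a collagen gene, rose by 1.41 ± 0.28 (adjusted p = 0.0435), and ACTA2 had 0.92 without passing (adjusted p = 0.17).

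At 24 h alone, the question was which genes differ after a day of starvation, and no single gene passed limma at an adjusted p under 0.05. The smallest adjusted p was 0.063, and 1928 genes had an unadjusted p under 0.05, of which 688 were higher, where chance would give 485. The genes with the largest differences are therefore given as values that did not pass. CTH had a scaled signal of 61.5 ± 22.3 (SD, n = 2) in control and 1496 ± 412 (SD, n = 2) in starved cells, a difference of 4.29 (adjusted p = 0.063). INHBE differed by 3.97, AQP9 by 3.90, CREBRF by 3.56, RFPL3S by 3.50, TNFRSF10D by 3.17 and CHAC1 by 3.15. PLK2, a polo-like kinase, differed by 3.06, ZBTB10 by 2.92 and ERC2 by 2.92. On the lower side MIR142 had -3.06, DTL, which helps degrade the replication licensing factor CDT1, had -2.96, CDCA7 had -2.93 and RNFT2 had -2.73. TRAF5 had -2.70, RITA1 -2.65, DPP3 -2.49, TMEM106C -2.47, SLC25A15 -2.46 and EMG1, a factor of ribosome assembly, -2.43. DTL differed by -1.51 in pair 1 and by -4.41 in pair 2.

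The count of 0 depended on the model and on single arrays. With a replicate block, fitted to the 24 h arrays alone, it was 1310 genes (486 higher, 824 lower). That fit has fewer residual degrees of freedom than the main fit. Without the starved array 1 it was 1361 genes (343 higher), and without the starved array 2 it was 672 (355 higher), each with the lone starved array assumed to vary like the control pair, and it was 2 without the control array 1. At least 2-fold in all 4 pairings of a starved with a control array, with no test, were 201 higher and 247 lower genes. Scaling to the hybridization controls gave 99 higher and 2380 lower genes. It moved the median of all genes by -0.571 at 24 h, -0.315 over both times and 0.215 at 6 h. The mean log2 of these probe sets was 9.60 and 9.27 on the control and 10.18 and 9.98 on the starved 24 h arrays. At 6 h it was 9.93 on the control and 9.69 on the starved array. Control arrays thus differed widely among themselves, and this scaling carries that spread into every gene.

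As lists, 10 of 27 passed camera with its preset correlation at 24 h, 8 higher and 2 lower, and the same 10 passed over both times. With an estimated correlation none passed, and neither did any with fry, whose mixed test for changes in either direction passed 9. The count was 17 with quantile normalization (8 higher, 9 lower) and with scaling to the hybridization controls (10 higher, 7 lower, relative to other genes), and 19 of 30 without a filter on signal (9 higher, 10 lower). It was 13 with the mean of all probe sets (10 higher, 3 lower), 11 with a replicate block (8 higher, 3 lower), and between 8 (6 higher, 2 lower) and 15 (7 higher, 8 lower) when 1 array was left out. After scaling to the hybridization controls, without taking off the shift of all genes, 4 of the 8 higher lists had a median below 0 at 24 h, with -0.35 for hypoxia, -0.31 for ribosomal proteins, -0.27 for autophagy and -0.07 for aminoacyl-tRNA synthetases. The higher lists were those of ATF4 (median 1.99), p53 (0.95), immediate early genes (0.78), NF-kB (0.64), aminoacyl-tRNA synthetases (0.56), autophagy (0.33), ribosomal proteins (0.33) and hypoxia (0.26). Their adjusted p with an estimated correlation was between 0.571 and 0.753. For autophagy (-0.0294) and p53 targets (-0.0156) the estimated correlation was below the preset 0.01. Correlation between genes therefore does not account for their failure in that test, which has few degrees of freedom. Adjusted over the list alone, 21 ATF4 genes were higher and 1 lower, 10 p53 targets were higher, 4 immediate early genes, 2 NF-kB targets and 3 hypoxia genes were higher, and 7 aminoacyl-tRNA synthetases were higher and 1 lower. The hypoxia list fell under the threshold without the starved array 1 (median -0.0029, adjusted p = 0.113) and without the control array 1 (adjusted p = 0.0676), and the NF-kB list without the control array 2 (adjusted p = 0.0993).

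Genes of autophagy, the process the treatment was meant to induce, had a median of 0.33 at 24 h and of 0.26, 0.43 and 0.30 in the 6 h pair and the 24 h pairs 1 and 2. Of 34 measured genes, 2 rose over both times. UVRAG, a partner of the autophagy kinase complex of Beclin 1, rose by 1.19 ± 0.21 (adjusted p = 0.0353) and MAP1LC3B, whose product coats autophagosomes, by 1.00 ± 0.21 (adjusted p = 0.0483). Adjusted over the list alone, 8 were higher over both times and none at 24 h. The cargo receptor SQSTM1 had 0.82, ATG5 had 0.36 and BECN1 had -0.18 over both times, and none of them passed (adjusted p = 0.0824, 0.422 and 0.677). GABARAPL1 and ULK1 had a mean signal of 14.4 and 34.5, below the 50 needed for testing. The list passed over both times with a preset correlation (adjusted p = 5.66e-05) and with fry (adjusted p = 0.0378), but not with an estimated correlation (adjusted p = 0.261). At 24 h the adjusted p was 0.000201 with the preset and 0.571 with an estimated correlation.

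MHC class II presentation, named in the title, was not shifted at 24 h (median -0.28, adjusted p = 0.182), and none of 14 measured genes passed at either contrast. Adjusted over the list alone, 2 were lower at 24 h. They were RFXANK, a subunit of the factor that switches on class II promoters, at -2.10 ± 0.38, and HLA-DMA, part of the peptide exchange factor, at -1.18 ± 0.30, both lower in both 24 h pairs. At 6 h these genes had -0.13 and 0.12. The class II chain gene HLA-DRA had 0.31 ± 0.22 and the invariant chain gene CD74 0.10 ± 0.25 at 24 h, and CD74 turned to -0.16 under quantile normalization. Their probe sets were brighter than 99.6% and 99.3% of genes, a range where arrays respond less to changes. CIITA, the class II master regulator, had -0.02 ± 0.51 with opposite signs in the 24 h pairs and under quantile normalization (0.17). The list passed camera under quantile normalization (adjusted p = 0.0308) and without a filter on signal (adjusted p = 0.01), both with a preset correlation. With an estimated correlation and the main processing, its adjusted p was 0.753. MHC class I genes had a median of 0.22 and a mean of -0.15 (adjusted p = 0.613), with PSMB9 at -1.11 and ERAP1 at -1.11, neither passing. In the 24 h pairs 1 and 2, PSMB9 had -0.30 and -1.93 and ERAP1 -0.80 and -1.42.

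**Figure D3:**
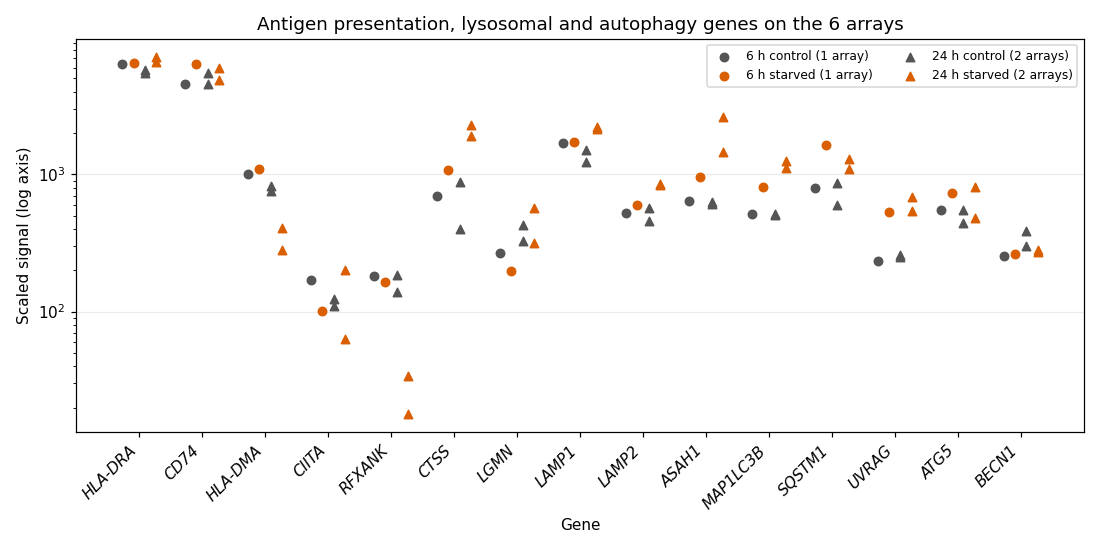
Scaled signal (log axis) of 15 genes of MHC class II presentation, the lysosome and autophagy on each of the 6 arrays, 1 point per array. HLA-DMA and RFXANK lie lower on both starved 24 h arrays than on both control 24 h arrays, MAP1LC3B, UVRAG, ASAH1 and CTSS lie higher, and HLA-DRA and CD74 stay among the brightest genes on all arrays.

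Lysosomal genes were not shifted at 24 h (median 0.03 over 29 genes, adjusted p = 0.0991), and none passed, also adjusted over the list alone. The largest differences were those of the protease gene CTSS, which trims the invariant chain, at 1.79 ± 0.40 (adjusted p = 0.114), and of the ceramidase gene ASAH1 at 1.64 ± 0.34 (adjusted p = 0.102). LAMP1 and LAMP2, membrane proteins of lysosomes, had 0.67 and 0.72, and the protease gene LGMN had 0.18, without passing. CTSD and CTSB, with a mean signal of 49.5 and 30.2, were below the 50 needed for testing.

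Genes of DNA replication were lower at 24 h, with a median of -1.61 over 29 genes. The list passed with a preset correlation (adjusted p = 4.57e-08) and not with an estimated one (adjusted p = 0.753). The median was -0.63 in pair 1, -2.12 in pair 2 and -0.24 at 6 h. CDC6, which loads the replicative helicase, fell by 1.82 ± 0.38 over both times (adjusted p = 0.0464). Over both times the list had an adjusted p of 6.76e-06 with a preset and 0.791 with an estimated correlation. CDC6 was the only gene of the list to fall, with 4 lower adjusted over the list alone and 15 at 24 h. RRM2, a subunit of ribonucleotide reductase, had -2.28 ± 0.76 at 24 h (adjusted p = 0.179), with a range of -3.59 to -0.98 over the alternatives. Mitotic genes parted the starved arrays. Their median was 0.55 in pair 1 and -1.35 in pair 2. The list did not pass camera (adjusted p = 0.279 with a preset and 0.873 with an estimated correlation). Its median was 0.58 without the starved array 2 and -1.35 without the starved array 1. CCNA2 and CDC20, regulators of mitotic entry and exit, had -1.38 and -1.25 at 24 h, and no mitotic gene passed in either correction. Over the alternatives CCNA2 ranged from -2.27 to -0.48 and CDC20 from -2.10 to -0.40.

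**Figure D4:**
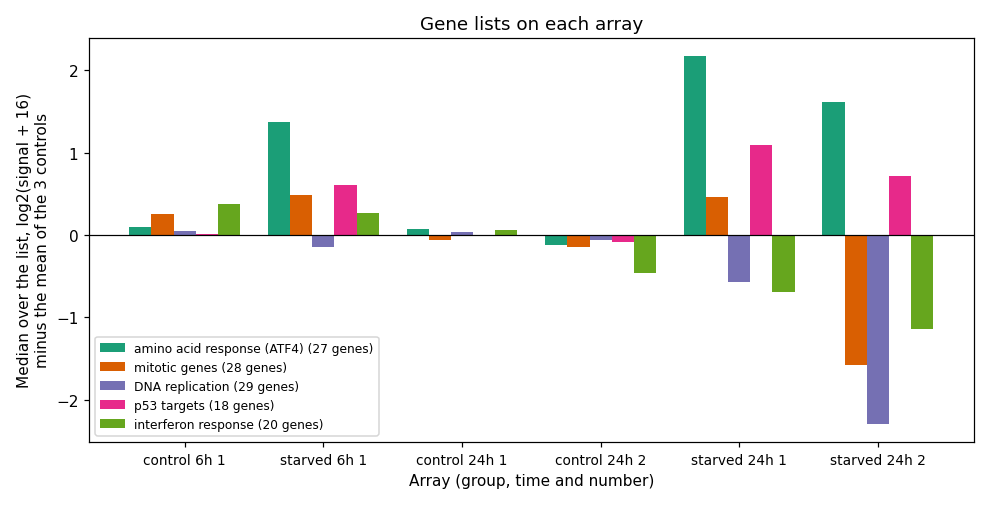
Median over each of 5 gene lists of log2(signal + 16) minus the mean of the 3 control arrays, 1 bar per list and array. The ATF4 list lies at 1.37, 2.17 and 1.62 on the starved arrays, and the mitotic genes at 0.49 and 0.46 on 2 starved arrays and at -1.58 on the starved 24 h array 2.

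The interferon response was lower at 24 h (median -0.59 over 20 genes, adjusted p = 0.00635 with a preset and 0.753 with an estimated correlation), without a gene that passed in either correction. The antiviral gene OAS3 had -1.95 and GBP1 -1.77. Over both times the adjusted p was 0.0433 with a preset and 0.791 with an estimated correlation. The list did not pass without the starved array 2 (adjusted p = 0.0722) or the control array 1 (adjusted p = 0.153). Ribosomal proteins had a median of 0.33 at 24 h (adjusted p = 2.42e-05 with a preset and 0.753 with an estimated correlation), and 27 of 32 genes were higher in both 24 h pairs, RPL11 at 0.66 and RPL19 at 0.57, none of them passing in either correction. Over both times the adjusted p was 9.14e-06 with a preset and 0.791 with an estimated correlation. Under quantile normalization the median was 0.0458 and the list did not pass (adjusted p = 0.109). Nor did it pass without the starved array 2 (adjusted p = 0.0681) or the control array 1 (adjusted p = 0.0612).

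The other lists did not pass at 24 h as analysed here, and several passed in alternatives that kept the preset correlation. Ribosome biogenesis had a median of -0.46 (adjusted p = 0.0709), with 1 of 23 genes lower adjusted over the list alone, MRTO4 at -1.56, NHP2 at -1.20 and MYC, a driver of ribosome production, at 0.10. Cholesterol synthesis had -0.50 (adjusted p = 0.0938), with DHCR7 at -1.62 and NSDHL at -1.53. DHCR7 ranged from -2.87 to -0.38 and NSDHL from -2.08 to -0.97 over the alternatives. Oxidative phosphorylation had -0.29 (adjusted p = 0.178), with NDUFA1 at -0.91 and NDUFV2 at -0.89. Over the alternatives NDUFA1 ranged from -1.65 to -0.18 and NDUFV2 from -1.03 to -0.75. The proteasome had -0.17 (adjusted p = 0.377), with PSMD8 at -1.84 and PSMB5 at -0.93, and cytosolic heat shock had -0.29 (adjusted p = 0.146), with DNAJB1 at -1.42 and HSPB1 at -1.20. These 5 lists passed, all lower, with quantile normalization (adjusted p = 0.0125, 0.0308, 0.00409, 0.0447 and 0.00961 in this order), without a filter on signal (adjusted p = 0.00103, 0.00131, 0.00869, 0.0454 and 0.0121) and with scaling to the hybridization controls (adjusted p = 0.0158, 0.00525, 0.0138, 0.0203 and 0.0434). Cholesterol synthesis also passed with a replicate block (adjusted p = 0.0338). Glycolysis (lower) and the FOXO list (higher) passed with quantile normalization (adjusted p = 0.0308 and 0.049) and without a filter (adjusted p = 0.0331 and 0.0461), and mitotic genes without a filter (lower, adjusted p = 0.0186). With the mean of all probe sets the FOXO list and apoptosis regulators passed, higher (adjusted p = 0.00292 and 0.0247), and heat shock passed, lower (adjusted p = 0.0328). With scaling to the hybridization controls the FOXO list and apoptosis regulators passed as higher relative to other genes (adjusted p = 0.0182 and 0.0391), while their medians were -0.32 and -0.52 and that of all genes -0.71. B cell identity had -0.21 (adjusted p = 0.483), where the transcription factor gene SPIB, at -1.86 ± 0.29, was the only gene lower adjusted over the list alone, and POU2AF1 had -0.89. Plasma cell genes had -0.30 (adjusted p = 0.518), with JCHAIN at -1.15 and MZB1 at -1.05. The 7 replication-dependent histone genes had a median of 0.05 and a mean of -0.12 (adjusted p = 0.742), with H1-2 at -0.93 and H2BC21 at -0.36. The reference genes GAPDH and ACTB had 0.28 and 0.47, without passing, and GAPDH was at -0.02 under quantile normalization.

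At 6 h there is a single pair of arrays, and genes at least 2-fold apart were counted. They were 526 (5.42% of the genes tested), 275 higher and 251 lower in starved cells. The count and its split depended on the processing. With scaling to the hybridization controls 448 were higher and 121 lower, with an offset of 50 these were 183 and 96, with an offset of 1 they were 333 and 395, and with quantile normalization 271 and 176. Without a filter they were 382 and 394, and with the mean of all probe sets of a gene 153 and 142. With a mean signal of at least 100, 244 of 377 were higher. In a test, limma with the spread of the 24 h pairs passed none, with 231 genes at an unadjusted p under 0.05, where chance would give 485. The control arrays of 24 h, which are replicates, had 500 genes at least 2-fold apart. That comparison crosses the array numbers, whereas both 6 h arrays are numbered 1. Between the control 6 h and control 24 h arrays numbered 1, which differ in time, 247 genes were at least 2-fold apart. CREBRF was 10.3-fold higher, with a scaled signal of 389.8 in the starved and 23.3 in the control sample, followed by TNFRSF10D (7.82-fold), ATF3 (7.59-fold), ZBTB10 (7.27-fold), PPP1R15A (7.21-fold), CHAC1 (7.18-fold), CCNG2 (6.90-fold) and INHBE (6.01-fold). MIR142 had a signal of 473.3 in the control sample and a difference of -2.89. Lower genes were also TMEM177 at -2.29, SLC25A15 at -2.21, PIGM at -2.19, MRPL20-AS1 at -2.13, PRUNE1 at -1.98, EOMES at -1.96 and FJX1 at -1.90. The medians of the ATF4, p53, immediate early and NF-kB lists lay above 100% of 10000 random lists of the same size matched on signal, with values of 1.20, 0.58, 0.58 and 0.66. The autophagy list lay above 99.99% (median 0.26), hypoxia genes above 99.98% (0.57) and mitotic genes above 99.43% (0.25). DNA replication genes lay above 0.09% of random lists (-0.24), and MHC class II genes above 27.7% (-0.03). Random lists lack the correlation within a list, estimated at 24 h as 0.97 for mitotic and 0.842 for DNA replication genes. These ranks come from 1 pair of arrays and cannot separate starvation from any other difference between these arrays.

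Genes that differed at 6 h mostly kept their direction at 24 h. Of the 275 higher genes 246 (89.5%) were higher in both 24 h pairs, against 27.2% of all genes, and of the 251 lower genes 188 (74.9%) were lower in both, against 42% of all. Across 9708 genes, which are not independent replicates, the 6 h and 24 h effects correlated with Pearson's r of 0.597 and Spearman's rho of 0.538. The r was 0.681 with pair 1 and 0.389 with pair 2, and it was 0.559 between the 24 h pairs. Without the starved 24 h array 1 the r of the mean effect was 0.372.

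No gene passed the test of a different starvation effect at 24 h and 6 h (limma, smallest adjusted p = 1). An unadjusted p under 0.05 was found for 113 genes, where chance would give 485. The fitted spread comes from the 24 h arrays alone, and a count below chance does not show that the effects were alike. As lists, 4 passed with a more positive and 5 with a more negative effect at 24 h under a preset correlation, and none with an estimated correlation (adjusted p = 0.773 for each of the 9). ATF4 genes differed by a median of 0.47, p53 targets by 0.41, aminoacyl-tRNA synthetases by 0.39 and ribosomal proteins by 0.17. DNA replication genes differed by -1.24, mitotic genes by -0.83, interferon genes by -0.65, heat shock genes by -0.64 and proteasome genes by -0.37. The value of the mitotic genes joins opposite signs, with an effect of 0.25 at 6 h, 0.55 in the 24 h pair 1 and -1.35 in the 24 h pair 2.

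From 6 h to 24 h in control medium no gene passed (limma, smallest adjusted p = 1). Here 114 had an unadjusted p under 0.05, where chance would give 485, so this does not show that genes were unchanged. Of the lists, 7 passed with a preset and none with an estimated correlation (adjusted p = 0.982 for each of the 7). Interferon genes had a median of -0.56 and mitotic genes of -0.38, while heat shock genes had 0.35, histones 0.72, ER chaperones 0.20, glycolysis 0.145 and cholesterol synthesis 0.08. From 6 h to 24 h of starvation no gene passed either (limma, smallest adjusted p = 0.755). An unadjusted p under 0.05 was found for 594, where chance would give 485. Without the starved 24 h array 1 the count was 448, of which 385 were lower at 24 h. With a term for the replicate number, chosen after the results were seen, 13 genes passed in control medium (9 higher and 4 lower at 24 h) and 34 in starvation (26 higher, 8 lower). Of the lists, 9 passed with a preset and none with an estimated correlation (adjusted p = 0.753 for each of the 9). Interferon genes had -1.16, DNA replication genes -1.31, mitotic genes -1.22, NRF2 targets -0.51 and MHC class II genes -0.43. Histones had 0.82, p53 targets 0.35, ATF4 genes 0.33 and ribosomal proteins 0.22. No 6 h array is numbered 2, so changes with time overlap with the array number. Relative to the controls, mitotic genes lay at 0.489 on the starved 6 h array. They lay at 0.457 on the starved 24 h array 1 and at -1.58 on array 2, so their fall rests on 1 array. Histone genes followed the number of the array, with a median relative to the controls of 0.904 and 1.31 on the arrays numbered 2 and of -0.38 to -0.781 on the others. Each of these fits assumes that the lone 6 h array varies like the 24 h arrays.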

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

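All tests of explanations in this part were chosen after the results were seen, while the test of the difference between the times was planned.

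Among the lists, 9 had a starvation effect that differed between 24 h and 6 h in camera's test of the difference with a preset correlation, and none did with an estimated correlation. The median difference was 0.475 for the ATF4 list, 0.407 for p53 targets, 0.388 for aminoacyl-tRNA synthetases and 0.173 for ribosomal proteins. It was -1.24 for DNA replication, -0.833 for mitotic genes, -0.645 for the interferon response, -0.637 for cytosolic heat shock and -0.372 for the proteasome.

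Among these lists, all 28 mitotic genes were lower on the starved 24 h array 2 than on array 1 once the same difference between the control arrays was taken off, with a median of -2.03, while the control arrays differed by -0.101. A batch shared by both arrays numbered 2 would make the starved and control differences equal, and the value of -2.03 argues against it as the whole source. The lowest of 10000 random lists matched on signal was at -0.707, which argues against a compression that depends on brightness. The ATF4 list lay 1.62 above the controls on this array, where the highest random list was at 0.64, which argues against a control sample under a starved label. A difference of that culture or of the handling of that array stays open, and no biological explanation was tested.

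Control probe sets outside the gene measurements also differed at 24 h. The 9 hybridization controls were higher by a mean log2 of 0.639 on the starved arrays (0.573 in pair 1, 0.706 in pair 2, -0.237 at 6 h), and the 6 probe sets for ribosomal RNA by 1.05 (0.0168 at 6 h). Degraded RNA would raise the 3' to 5' ratios. Those of GAPDH and ACTB, both bright, differed by 0.121 in log2 and were at most 1.17, which argues against degradation for these transcripts. The dimmer control ISGF3A was not part of this test, and its 3' signal was well above its 5' signal. At 24 h these were 913.6 and 679 against 140.6 and 125.7 on the starved arrays. On the control arrays they were 1571.6 and 1060 against 295.4 and 227.5. A smaller share of polyadenylated RNA in starved cells was predicted to place these controls higher on all starved than on all control arrays. This did not hold at 6 h, with a mean log2 of 9.69 on the starved and 9.93 on the control array. Hybridization controls are added after labelling, so they need not follow that share, and their values do not test it. At 24 h such a share cannot be told apart from a difference in labelling or hybridization, and the control probe sets cannot decide between them. The exact permutation test (two-sided) of the hybridization controls over 3 starved and 3 control arrays gave p = 0.2, and that of the ribosomal RNA 0.1, the smallest p possible.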

How the results depend on the processing

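Scaling to the hybridization controls, leaving out both arrays numbered 2, the replicate block for contrasts with time, and all alternatives for lists over both times were chosen after the results were seen, and the other alternatives were planned. The planned block for chip lot, hybridization or scan could not be run, because these fields are empty. Signal near background limits the values of dim genes, and the filter on the mean of 6 arrays kept genes that were dim in 1 group, such as RFPL3S (5.3 and 7.4 on the control 24 h arrays). The 63 named genes called over both times kept their sign in all of up to 17 alternatives. Where arrays were scaled to the hybridization controls, signs are relative to the shift of all genes. Each of the 63 lost its call in at least 1 alternative. That was fixed in advance, because no gene passed without the starved or the control 6 h array, and it does not describe single genes. For 33 of the 63 the largest change was more than 1.5 times the smallest, and at most 3.5 times (PWP2). Counting each named gene or list under each alternative, direction and side of the threshold stayed in 1451 cases for genes at 24 h (363 newly past it, 21 turned), 1573 for genes over both times (77 newly past it, 419 no longer, 12 turned), 348 for lists at 24 h (40, 28 and 16) and 77 for lists over both times (3, 19 and 9). The counts for the difference between the effects (0) and for both comparisons between times (0) were unchanged in the alternatives run for them but those given here, and they were not run without a 6 h array or without both arrays numbered 2. Where fewer arrays or genes were used, power differed by construction, and elsewhere the cause was not tested.

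Genes called at 24 h (0 as reported) were 9 with quantile normalization, 2 each with an offset of 50, no filter on signal or a mean signal of at least 100, 1310 with a replicate block (486 higher, 824 lower), 448 at least 2-fold in all 4 pairings, 2479 with scaling to the hybridization controls, and 0 to 1361 leaving out 1 array. Genes over both times (301) were 88 without a filter, 94 with the mean of all probe sets, 110 without a trend, 1002 with a replicate block, 712 with scaling to the hybridization controls, 1600 without the arrays numbered 2, and 0 to 1015 leaving out 1 array. The block assumes that equal numbers pair the arrays, which the labels do not state, and the deviations of the 24 h arrays from their group means correlated at 0.385 between starved and control. Genes at least 2-fold apart at 6 h (526) were 279 with an offset of 50 (183 higher, 96 lower), 569 with scaling to the hybridization controls (448 higher, 121 lower), 295 with the mean of all probe sets and 0 past limma's threshold with the spread of the 24 h pairs. Genes changed from 6 h to 24 h were 3 in control medium with scaling to the hybridization controls, 13 in control medium and 34 in starvation with a replicate block, and 0 to 448 in starvation leaving out 1 of the 24 h arrays. Lists at 24 h (10, of which 2 lower) were 17 with quantile normalization (9 lower), 19 without a filter (10 lower), 17 with scaling to the hybridization controls (7 lower), and 0 with an estimated correlation and with fry. Lists over both times (10) were 0 with an estimated correlation and 1 with fry. The correlation of the 6 h and 24 h effects (0.597) was 0.372 to 0.687 leaving out 1 array.

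Most results that turned in sign or in the direction of the list test were below the threshold as reported. The exceptions were the hypoxia list at 24 h, with a median of -0.0029 without the starved array 1 (adjusted p = 0.113, where the alternatives ranged from 0.000139 to 0.71), and lists scaled to the hybridization controls without taking off the shift of all genes, where 4 of 8 higher lists at 24 h and 2 of 8 over both times had medians below 0 (autophagy -0.00806 and ribosomal proteins -0.123). With quantile normalization, values at 24 h were 0.053 for PRF1, -0.16 for CD74, 0.17 for CIITA, -0.020 for GAPDH and a median of 0.0317 for MHC class I, and over both times -0.020 for HLA-DRA and 0.039 for LGMN. CIITA at 24 h was 0.011 with an offset of 50, and CD74 was -0.056 with the mean of all probe sets. The list tests of MHC class I (median 0.217) and histones (0.0455) at 24 h turned without a filter and with fry. That of MHC class I also turned with scaling to the hybridization controls (median 0.155 after taking off the shift of all genes). Over both times that of NRF2 (-0.0782) turned with fry, and that of histones (-0.0726) with fry and a replicate block. Without the arrays numbered 2, values over both times were 0.11 for NDUFA1, and medians -0.176 for MHC class II, 0.0125 for glycolysis, 0.407 for mitotic genes (adjusted p = 1.72e-06), 0.0609 for the proteasome, 0.0275 for oxidative phosphorylation and 0.105 for heat shock.

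Leaving out 1 array gave these ranges at 24 h: H1-2 -2.33 to 0.46, H2BC21 -1.21 to 0.49, PRF1 -0.42 to 0.21, CIITA -0.75 to 0.70, ATG5 -0.034 to 0.71, CD74 -0.046 to 0.25, LGMN -0.22 to 0.59, MYC -0.50 to 0.71, GAPDH -0.031 to 0.59 and ACTB -0.0044 to 0.94. For list medians they were 0.00385 to 0.147 for MHC class I, -0.116 to 0.306 for ER chaperones, -1.35 to 0.577 for mitotic genes, -0.386 to 0.0562 for the proteasome, -0.548 to 0.0899 for oxidative phosphorylation, -0.506 to -0.0896 for NRF2 and -1.21 to 0.843 for histones. Over both times they were -0.30 to 0.18 for LGMN, -0.48 to 0.21 for MYC, -0.71 to 0.12 for CIITA and -1.55 to 0.051 for H1-2.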

Other observations

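The tests of the ribosomal proteins in this part were chosen after the results were seen, and the bound of the test on brightness and the measure and rule of the test on scaling were changed after their values were seen, while the counts over other splits of the arrays were planned.

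Ribosomal proteins and ribosome biogenesis had medians of opposite sign over both times, 0.222 and -0.279, and the difference between these lists was not tested. Among 32 ribosomal protein genes 20 were higher in all 3 pairs and 0 lower in all 3, and among 23 biogenesis genes 2 were higher and 11 lower in all 3. The median of the ribosomal proteins lay above 98.57% of random lists matched on signal, which leaves open whether brightness accounts for part of it. Scaling to the hybridization controls moved all genes together, to a median of -0.123 for the list and -0.441 for all genes, and the list lay 0.318 above all genes, against 0.348 with the authors' scaling. With quantile normalization the median was 0.0274, or 0.106 above all genes, which leaves open whether ribosomal proteins rose or other genes fell.

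With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. The fits of the other splits held no term for starvation, so its effect stayed in their residual spread. This makes fewer calls of genes likely for them, and their counts do not show what chance alone gives. For genes over both times the real split gave 301 and the highest of the others 45, so that 1 split reached the real count. For lists the real split gave 10 and the highest of the others 14, and 7 splits, the real split included, gave at least 10. The splits that put both arrays numbered 2 in the same group gave 10, 13, 8 and 12 lists, and the remaining splits other than the real gave 14, 12, 9, 8 and 11. With a term for the replicate number the real count was 10.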
